A study of Mus musculus with 40 samples.

How the data were processed

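Per the labels, female C57BL/6 mice of 5 to 7 weeks, kept on a 12 h light and dark cycle, received 1 intratracheal instillation of 8 nm anatase TiO2 nanoparticles in 40 µl. Lung, liver and heart were removed and snap frozen, and RNA was taken from random sections of lung with Trizol and RNeasy columns (integrity number above 7). For each array 200 ng of RNA was labelled, lung RNA with Cy5 and a reference RNA of 11 mouse cell lines with Cy3. The groups used here were 0, 54, 162 and 486 µg on days 1 and 28, with 5 mice per group, 8 groups and 40 arrays. The labels give no replicate numbers, so mice were numbered here within each group in the order of the samples. A dose of 18 µg and a day 90 named in the series description were not analysed here. What the control mice were instilled with, the surface modification named in the title and the times of day at which tissue was taken are not given in the sources used here.

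The arrays were Agilent whole-genome mouse arrays with 45018 spots, and per the file headers they were scanned on an Agilent scanner and extracted with Agilent Feature Extraction 11.0.1.1. Per the file headers the spot and local background signals of each channel are intensity values, given as medians over the pixels of a spot. The log ratio column is, per the file headers, a log10 ratio of processed red to green signal after the software's own background subtraction and dye normalization. Other columns are flags that, per the file headers, mark spots as saturated, above background or uneven. The deposited matrix of the authors holds log2 ratios; its scale, its normalization and its direction are not given in the sources used here. From the values, the deposited log2 ratios are positive where the lung signal exceeds the reference, are centred near 0 on each array (array medians −0.036 to −0.016) and correlate with the ratios computed here with r from 0.990 to 0.996 across probes of an array.

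The median signals were used because the files hold no mean spot signals, which had been planned. Background was corrected with normexp (saddle fit, offset 50) in limma 3.58.1 under R 4.3.3, and files were read with data.table (1.17.8). Spots flagged in either channel as uneven or as population outliers were left out (63 to 127 gene spots per array), and each array was normalized by loess on gene spots with control spots at weight 0. The choices in this section were made before the data were examined, except where stated.

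The background handling departs from the plan as fixed. With each spot's own local background, the normexp fit failed on 5 arrays: the log of its noise parameter was 4.50 to 7.53 (Cy5) and 5.12 to 7.85 (Cy3), against medians of 0.383 and 0.0499 on the other arrays, of which 1 reached 4.92 in Cy5. On these 5 arrays the ratios correlated with the authors' deposited log2 ratios with r from 0.403 to 0.954 (median 0.780), against 0.983 to 0.996 on the rest. A spot whose local background exceeds its signal by more than 30 units was therefore given the median background of the array, which concerned 45 Cy5 and 31 Cy3 values on 9 arrays and at most 19 values per array. This change was made after the counts under the planned handling had been seen, which were 0, 0 and 13 genes at 54, 162 and 486 µg on day 1, 0, 0 and 5 on day 28, 3 for the difference between days at 486 µg and 23 between control mice. The other handlings tried before it was chosen were the maximum likelihood fit of normexp, clipping of the differences, and limits of 20, 50, 100 and 300 units. Results under the planned handling, under the maximum likelihood fit and under the limit of 100 units are given with the alternatives.

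Spots of a probe were averaged (43379 gene spots, 41174 probes). Gene symbols came from a RefSeq table of assembly GRCm38.p6 through the accession of each probe, which named 27479 probes with 18749 symbols and left 13695 without a symbol; the array annotation is on another build, so no coordinates are given. Each gene was represented by its probe with the highest mean Cy5 signal (32111 features). A feature was tested where its probe stood above background in Cy5 on at least 4 of 5 arrays of at least 1 group, which left 20726 features, 14690 with a symbol. Median signals were 116 to 166 units in Cy5 and 61 to 85.5 in Cy3, and 61.0 to 72.9% of spots stood above background in Cy5. A gene near background can therefore show only a lower bound of a fold, and arrays measure no absolute abundance. Arrays of 1 group correlated with r from 0.914 to 0.987 (80 pairs), and no 2 arrays were identical.

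The arrays sat on 10 slides of 4, each with 1 array per dose of 1 day, scanned on 3 dates. A linear model over all 40 arrays with the 8 groups and slide as a fixed block was fitted with limma (24 residual and 3.76 prior degrees of freedom), and the Benjamini-Hochberg adjusted p was set at 0.05 per comparison. The 12 comparisons were each dose against the control mice of its day, the difference of each dose effect between days, 486 against 162 µg on each day, and control mice of day 28 against day 1. The last used only the 10 control arrays, with no block. All p values are two-sided unless stated.

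A total of 35 gene lists were fixed in advance, covering acute phase proteins, chemokines, cytokines, matrix and fibrosis, markers of immune, airway, alveolar, vascular and connective tissue cells, tissue that can be taken with lung, and stress, metabolic and clock responses. They were tested with camera (preset correlation 0.01) in 7 comparisons and adjusted over all 245 tests, with an estimated correlation and fry as alternatives. In 29 of the 245 tests the median, the mean and the direction of the test differed in sign, 0 of them among the lists called. Named genes are the 10 largest rises and 10 largest falls at 486 µg among genes past the threshold with 1 sign on all 5 slides and a symbol (5 each way in other comparisons, for control mice without overlap of the 2 groups), up to 4 members of a list by smallest p, and a panel of 30 genes fixed in advance. Of the panel, Cxcl2, Ccl22 and Csf3 did not stand above background and were not tested. Values of some list members are not reported here.

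Shared effects of 162 and 486 µg were compared with 100 simulations of unchanged doses and with 10 splits of the control mice, and calls of the 2 days at 486 µg with Fisher's exact test. Alternatives fixed in advance were no slide block, slide as a random block, no background correction, the software's log ratio, between-array quantile normalization of average signals, Cy5 alone, the authors' deposited matrix, no filter, a filter on all 40 arrays, the mean of all probes of a gene, moderation with an intensity trend, the compared groups alone, single scan dates and leaving out each array. Alternatives chosen after seeing the data were the other background handlings, leaving out the 5 arrays with a failed background fit, leaving out 3 arrays rich in muscle transcripts, and a covariate made of the genes that differ between control mice. The procedure was tested on simulated data. Of 100 genes changed by 1 and 100 by 2 log2 units, 98 and 99 were called. There were 10 false among 207 calls and 0 calls in an unchanged comparison. The 1 list moved was found with 0 others of 245 tests, where its own test of the difference between days was not counted. The simulated genes varied independently of each other, and each had the same spread in all groups. The simulation therefore cannot tell how often genes or lists that vary together are called falsely. Nor can it tell this for genes whose spread differs between groups.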

Results

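Lungs of female C57BL/6 mice were compared after a single intratracheal instillation of 8 nm anatase TiO2 nanoparticles at 0, 54, 162 or 486 µg, on day 1 and on day 28. Each of the 8 groups held 5 separate mice, and each mouse had 1 array on which lung RNA was measured against a reference RNA pooled from 11 mouse cell lines. The series title names the question of fibrosis-like changes at high dose. Between 61.0 and 72.9% of spots (median 66.4%) stood above background in the lung channel of an array, and 20726 gene features were tested. Values below are log2 differences from control ± standard error, fitted with limma with slide as a block, with n = 5 mice per group. The standard error of a gene rests on 1 spread pooled over all groups, except in the comparison of control mice. Spread was unequal for some genes. Timp1, for example, had standard deviations of 1.63 at 486 µg and 2.08 at 162 µg on day 1. Those of Timp1 were 0.35 in day 1 control mice and 0.15 to 0.26 on day 28. For such genes, the standard errors and adjusted p of the day 1 doses can be too small. Each slide carried 1 array of every dose of 1 day, so that a count such as 5 of 5 slides gives how many slides showed the direction named. The labels give no replicate numbers, and those used below follow the order of the samples within a group.

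At 486 µg on day 1, transcripts of acute phase proteins, chemokines and matrix-associated proteins were among the largest rises called. Saa3, a serum amyloid A made in inflamed tissue, was 37.6-fold above control (log2 5.23 ± 0.86), Saa1 8.47-fold (3.08 ± 0.51) and Lcn2, an iron-sequestering protein of neutrophils and epithelium, 4.77-fold (2.26 ± 0.37). Timp1, an inhibitor of matrix metalloproteinases, rose 10.6-fold (3.40 ± 0.59), and Spp1, the secreted phosphoprotein osteopontin, 3.90-fold (1.96 ± 0.31). The monocyte attractants Ccl7 and Ccl2 rose 6.83-fold (2.77 ± 0.52) and 6.40-fold (2.68 ± 0.49), and the neutrophil attractant Cxcl1 4.34-fold (2.12 ± 0.32). Pbp2 rose 4.63-fold (2.21 ± 0.38) and Acod1, the itaconate-making enzyme of activated macrophages, 4.43-fold (2.15 ± 0.50). All 10 were higher on 5 of 5 slides, which the choice of named genes required, with adjusted p from 0.00189 (Cxcl1, Spp1) to 0.0119 (Acod1). Single mice moved some of these folds by more than 1.5 times. Without 486 µg replicate 4, Saa3 was 69.8-fold above control (log2 6.13), Timp1 18.2-fold (4.19), Saa1 12.9-fold (3.69), Ccl7 10.6-fold (3.41) and Ccl2 10.2-fold (3.35). Without control replicate 1 Saa3 was 61.6-fold above control (5.95), and without 486 µg replicate 1 Acod1 was 2.57-fold above it (1.36).

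The falls at 486 µg on day 1 were smaller. Bcan, a proteoglycan, fell 2.40-fold (log2 −1.26 ± 0.24, adjusted p = 0.00365), Rmrp, the RNA of a ribonuclease, 2.39-fold (−1.25 ± 0.31, adjusted p = 0.0163) and Cst8 2.35-fold (−1.24 ± 0.24, adjusted p = 0.00471). Krtap17-1 fell by 1.09 ± 0.22, Mamdc2 by 0.96 ± 0.18, Igfbp3, a binding protein of insulin-like growth factors, by 0.88 ± 0.22, and Npr3, the clearance receptor of natriuretic peptides, by 0.87 ± 0.18. Cdh16 fell by 0.82 ± 0.19, Taf15 by 0.81 ± 0.25 (adjusted p = 0.0487) and Thbs3, a thrombospondin, by 0.77 ± 0.12 (adjusted p = 0.00189). Each of these 10 was lower on 5 of 5 slides, again by the choice of named genes.

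In total 1366 genes changed at 486 µg on day 1 (825 up, 541 down; 1127 with a gene symbol), of which 63 rose and 4 fell by more than 2-fold, and 923 had 1 sign on all 5 slides. Normexp on each spot's own local background, which was the setting chosen before the data were examined, gave 13 genes. The setting behind 1366 replaces a few faulty background values and was chosen after those 13 had been seen. The count varied with the mice included. It was 266 without 486 µg replicate 1, 334 without replicate 2, 878 without replicate 5, 2428 without replicate 4. It was 796 without control replicate 2 and 552 without control replicate 5. Within scan date 1 the count was 1970 and within scan date 2 it was 0, while scan date 3 held 1 slide of the day. Without the slide block it was 670, and with only the control and 486 µg arrays of the day in the fit 0. Without the 5 arrays whose background fit had failed it was 231, and with a covariate, a score of the genes that part control mice of the 2 days, 65.

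Gene values on the 3 scan dates (1, 2 and 3) had 1 direction but differed in size. On either day, date 1 held replicates 2 and 5 of each group, date 2 replicates 3 and 4, and date 3 replicate 1. A difference between dates can therefore come from single mice as well as from the scan. Saa3 gave 6.13, 4.63 and 4.64, Timp1 4.32, 1.85 and 4.68, and Saa1 3.80, 2.38 and 3.07. Ccl2 gave 3.82, 0.92 and 3.90, Ccl7 4.08, 0.97 and 3.76. Lcn2 gave 2.21, 1.88 and 3.09, Cxcl1 2.42, 1.69 and 2.37, and Spp1 2.50, 1.41 and 2.00. Leaving out single arrays was run for the 20 genes above and the 11 further panel genes called at this dose and day. Of these 31 genes, 22 stayed past the threshold whichever of the 10 arrays was left out. Acod1 lost its call without 486 µg replicate 1 (adjusted p = 0.0648). Rmrp lost it without 486 µg replicate 1 (0.0621) or control replicate 4 (0.0610). Igfbp3 lost it without 486 µg replicate 1 (0.0551), 486 µg replicate 2 (0.0827) or control replicate 2 (0.0512), and Cdh16 lost it without 486 µg replicate 2 (0.0710) or control replicate 2 (0.0527). Taf15 lost its call without any 1 of the 10 arrays, with adjusted p from 0.0502 to 0.176, and was 0.05 lower with the covariate.

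**Figure D1:**
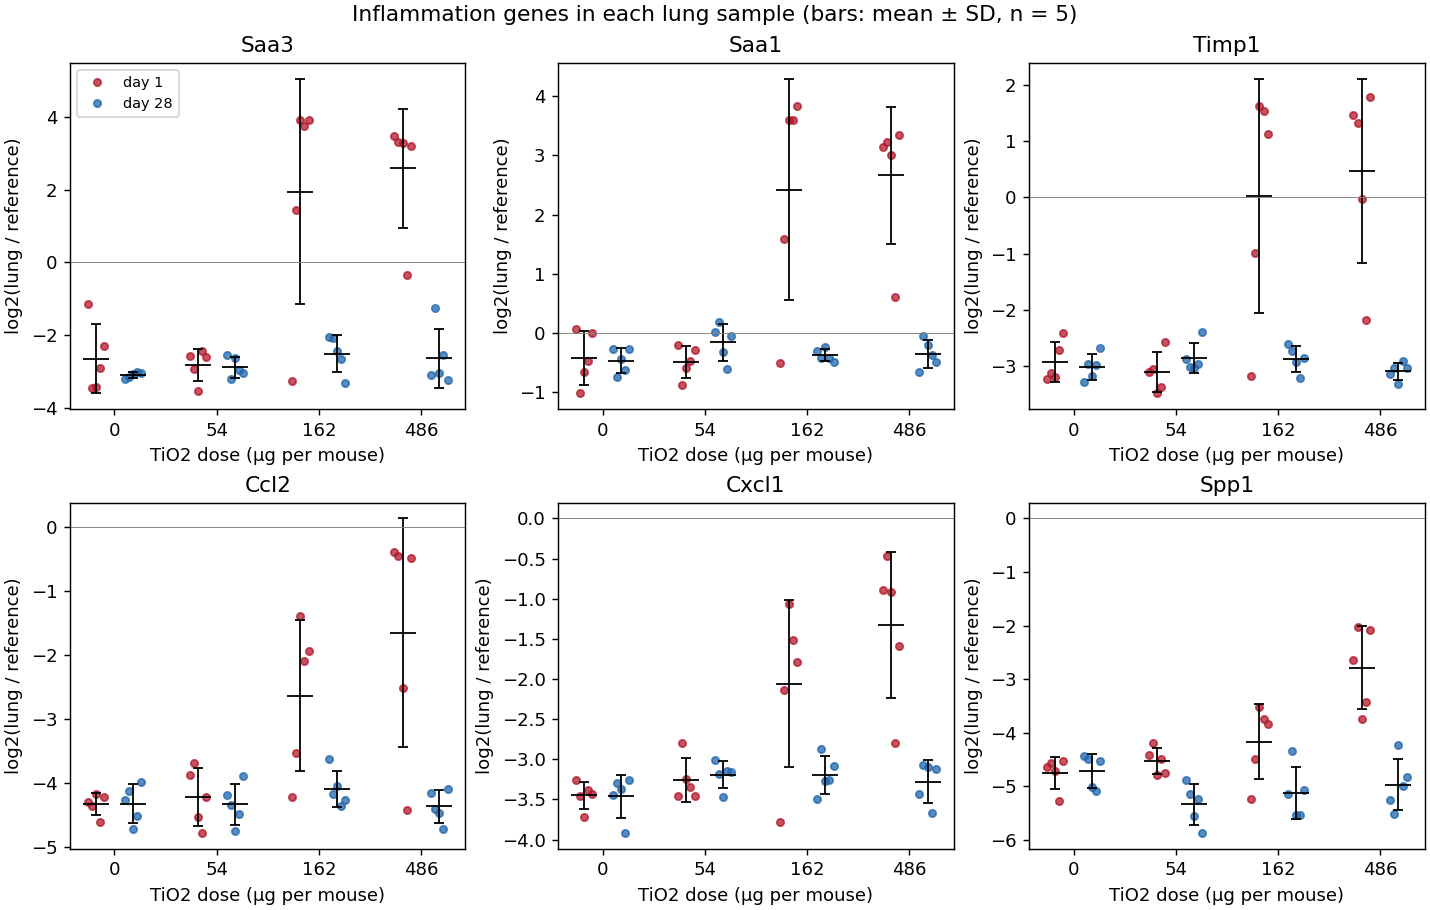
Log2 ratio of lung to reference RNA for inflammation genes on each array, by dose (µg) and day, with group means and standard deviations. On day 1, Saa3 averaged −2.65 ± 0.95 in control mice and 2.59 ± 1.64 at 486 µg; on day 28 the means of the 4 doses lay between −3.10 and −2.51.

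Among the gene lists fixed in advance, acute phase proteins moved most at 486 µg on day 1: 9 of 19 measured members rose and 0 fell (13 adjusted over the list alone). They included Saa2, Orm1, Orm2, Serpina3n and C3 (0.75) beside Saa1, Saa3 and Lcn2. The list median was 0.81, higher on 5 of 5 slides and 0.81, 0.58 and 0.73 on the 3 scan dates (adjusted p = 2.1e-11 with a preset correlation). Adjusted p was 0.742 with an estimated correlation. Saa2 rose by 1.91 (adjusted p = 0.00189) and Orm1, orosomucoid, by 1.55 (adjusted p = 0.00458). Liver makes many of these proteins, and the median of 25 other liver transcripts was 0.43 higher in these samples, with 24 of 25 higher and 0 called. With the covariate named above, Saa3 (5.03, adjusted p = 0.0401) and Saa1 (3.03, adjusted p = 0.0401) stayed past the threshold, as did 4 of the 9 called acute phase genes in all.

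Chemokines and cytokines rose as lists. Of the CC chemokines, 7 of 18 rose (Ccl2, Ccl3, Ccl4, Ccl7, Ccl9, Ccl12 and Ccl17) and Ccl27a fell (10 adjusted over the list alone; median 0.48, 5 of 5 slides, adjusted p = 5.7e-05). Adjusted p was 0.869 with an estimated correlation. Of the CXC chemokines, 4 of 13 rose (5 adjusted over the list alone; median 0.27, 5 of 5 slides, adjusted p = 0.00189, and adjusted p = 0.943 with an estimated correlation), with Cxcl10 at 1.92 (adjusted p = 0.00469, 4 of 5 slides) and Cxcl5 at 1.90 (adjusted p = 0.0217). Cxcl5 lost its call without 486 µg replicate 1 (adjusted p = 0.117) or 2 (0.0943), or control replicate 2 (0.0764) or 3 (0.0530). Of the inflammatory cytokines and growth factors, 6 of 15 rose: Il11, Csf2, Tnf, Csf1, Il6 and Il33 (10 adjusted over the list alone, median 0.45, 4 of 5 slides, adjusted p = 3.3e-04). Adjusted p was 0.742 with an estimated correlation. Their median was 0.58, 0.06 and 0.47 on the 3 scan dates. Il6 was at or under background on all 5 control arrays and above it on 4 of 5 treated arrays. It was at least 1.49-fold higher (adjusted p = 0.0130), and lost its call without 486 µg replicate 1 (0.0891) or 2 (0.0725). Ccl17, an attractant of T cells, rose by 1.53 (adjusted p = 0.00282), and Il1b was 0.88 higher (adjusted p = 0.0684, 4 of 5 slides). With the covariate Ccl2 (2.53, adjusted p = 0.0636) and Ccl7 (2.51, adjusted p = 0.0777) lost their calls, and Cxcl1 kept it (2.00, adjusted p = 0.0401).

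Genes of phagocytes moved as well. Lysosome and phagocyte lipid genes had 10 of 34 members up, among them Cd63, Gpnmb, Ctsk, Ctsb and Trem2. Abcg1 and Hexa fell (17 adjusted over the list alone; median 0.16, 4 of 5 slides, adjusted p = 0.0187). This became adjusted p = 0.982 with an estimated correlation. Of the markers of alternatively activated macrophages, Il4ra, Arg1 (1.51, adjusted p = 0.0124) and Msr1 rose and Rnase2a fell, of 16 measured (6 adjusted over the list alone; median 0.23, 4 of 5 slides, adjusted p = 0.0187). Adjusted p was 0.982 with an estimated correlation. Arg1 was 2.40, 0.28 and 2.20 higher on the 3 scan dates, and its adjusted p passed 0.05 without 486 µg replicate 1 (0.0714), 2 (0.0739) or 5 (0.0511) or control replicate 5 (0.0522). In the same list Retnla was 0.22 higher (adjusted p = 0.763) and Chil3 0.32 higher (adjusted p = 0.461). Neutrophil markers had 4 of 24 members up (Lcn2, Clec4e, Il1r2 and Cxcr2) and Fpr1 down (10 adjusted over the list alone; median 0.38, 5 of 5 slides, adjusted p = 0.00231). Adjusted p was 0.982 with an estimated correlation. Monocyte and macrophage markers missed the list threshold (adjusted p = 0.0534) with Cd14, C3ar1, Cd300lf, Clec4n and Ms4a6d up of 26 (10 adjusted over the list alone). Gpnmb, a lysosomal membrane protein of macrophages, rose by 1.19 (adjusted p = 0.00263).

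Genes of matrix, fibrosis and remodelling went both ways at 486 µg on day 1. Of 56 measured, 10 rose (among them Spp1, Timp1, Tnc, Tgfbi, Mmp14, Vcan and Tgfb1) and 4 fell (Postn, Fbln1, P4ha1 and Col6a3). There were 21 adjusted over the list alone, with a list adjusted p of 0.0582. Tnc, a matrix glycoprotein of injured tissue, rose by 1.27 (adjusted p = 0.00503, 4 of 5 slides; 2.11, 0.10 and 1.93 on the 3 scan dates). The fibrillar collagens Col1a1 (0.08 ± 0.12, adjusted p = 0.750) and Col3a1 (0.00 ± 0.21) were not called, and Mmp12 was at least 1.18-fold higher (adjusted p = 0.344), with 0 control and 3 treated arrays above background. Fibroblast, smooth muscle and pericyte markers had 0 up and 4 down of 22 (Postn, Pdgfra, Macf1 and Fgf10; 5 adjusted over the list alone; list adjusted p = 0.161).

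Cholesterol synthesis and uptake genes rose in small steps: 11 of 26, among them Fdps (0.54), Idi1 (0.59), Hmgcs1 (0.38), Lss, Cyp51 and Mvd. There were 15 adjusted over the list alone, with a median of 0.28 on 5 of 5 slides (adjusted p = 3.8e-08). Adjusted p was 0.869 with an estimated correlation. B cell and plasma cell markers had 2 of 17 up, Fcer2a (0.63) and Spib (0.56), with 4 adjusted over the list alone (median 0.32, 5 of 5 slides, adjusted p = 2.2e-04). Adjusted p was 0.982 with an estimated correlation. Interferon response genes had 3 of 33 up, Zbp1 (1.11), Isg15 (1.07) and Tap1 (0.41), also 3 adjusted over the list alone. The list median was 0.11 but higher on 2 of 5 slides, and 0.34, −0.17 and 0.21 on the 3 scan dates (adjusted p = 0.0206). Adjusted p was 0.993 with an estimated correlation. Cell division genes shifted up as a list with 0 of 38 members called, and 0 adjusted over the list alone. Mcm2 was 0.65 higher, and the median was 0.51, −0.07 and 0.32 on the 3 scan dates (0.23 pooled, 4 of 5 slides, adjusted p = 3.1e-04). Adjusted p was 0.993 with an estimated correlation. The rotation test fry called 4 lists at this dose and day: acute phase proteins (adjusted p = 0.00354), CC chemokines (0.0414), cytokines (0.00467) and cholesterol genes (0.0414).

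Other lists did not shift as a whole at 486 µg on day 1, although single members moved. In the oxidative stress and metal response list (adjusted p = 0.411), Hmox1, heme oxygenase 1, rose by 1.71 (adjusted p = 0.00810), and Mt2, a metallothionein, by 1.66 (adjusted p = 0.0198). Sod2, Srxn1 and Slc39a14 also rose and Gstm1 fell, of 28 measured (7 adjusted over the list alone). Hmox1 was 0.45 higher (adjusted p = 0.375) with the covariate named above. Mt2 lost its call without 486 µg replicate 1 (adjusted p = 0.127) or 2 (0.0904) or control replicate 2 (0.0523) or 5 (0.0523). Surfactant gene Sftpc was 0.21 lower (adjusted p = 0.593) and the club cell gene Scgb1a1 0.08 lower (adjusted p = 0.852). Immune cell lists with 0 members called were T cell markers (20 measured, 0 adjusted over the list alone, list adjusted p = 0.357) and NK cell markers (15 measured, 0 so adjusted, 0.418). Others were dendritic cell and antigen presentation genes (20 measured, 2 so adjusted, 0.0609) and eosinophil and mast cell markers (8 measured, 0 so adjusted, 0.887). Lists of tissue that could be taken with lung also had 0 members called: heart muscle (13 measured, 0 adjusted over the list alone, list adjusted p = 0.335) and skeletal muscle (11 measured, 0 so adjusted, 0.973). The others were fat (10 measured, 0 so adjusted, 0.727), thymus (2 measured, 0 so adjusted, 0.927) and red blood cells (6 measured, 0 so adjusted, 0.530). For fat, the median was 0.01 and the mean −0.03.

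At 162 µg on day 1, acute phase and chemokine transcripts were again among the genes called. Timp1 rose 7.75-fold (2.95 ± 0.59, adjusted p = 0.0357), Lcn2 3.74-fold (1.90 ± 0.37, adjusted p = 0.0329) and Ccl17 by 1.37 ± 0.28 (adjusted p = 0.0357). Clec5a, a receptor of myeloid cells, rose by 1.14 ± 0.24 (adjusted p = 0.0386) and the complement factor C3 by 1.06 ± 0.20 (adjusted p = 0.0314). Each rose on 5 of 5 slides, which the choice of these genes and of the falls below required. Saa3 (4.59 ± 0.86, adjusted p = 0.0311), Saa1 (2.84 ± 0.51, adjusted p = 0.0222), Saa2 (1.57 ± 0.31, adjusted p = 0.0329) and Gpnmb (0.97 ± 0.21, adjusted p = 0.0440) rose on 4 of 5 slides. On scan dates 1, 2 and 3, Saa3 was 5.55, 6.99 and −2.12 and Timp1 2.84, 4.53 and 0.04, where date 3 was replicate 1 alone. Without 162 µg replicate 1, Saa3 was 6.11, Timp1 3.81 and Saa1 3.68. Without replicate 4 of that dose Saa3 was 3.91 (adjusted p = 0.246) and Timp1 2.35 (adjusted p = 0.248), and without control replicate 1 Saa3 was 5.30. Falls were Cst8 (−1.18, adjusted p = 0.0386), Npr3 (−0.89, adjusted p = 0.0357), Arl4d (−0.60, adjusted p = 0.0440), Arrdc3 (−0.48) and Vgll3 (−0.40), on 5 of 5 slides each. Panel genes not called included Cxcl1 (1.39, adjusted p = 0.0511), Cxcl5 (1.82, 0.0779), Ccl2 (1.70, 0.0961), Ccl7 (1.74, 0.113) and Spp1 (0.58, 0.385).

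The count at 162 µg on day 1 was 50 genes (36 up, 14 down; 41 with a symbol), 12 up and 1 down by more than 2-fold, 39 with 1 sign on all slides. It depended on single mice, with 1035 without 162 µg replicate 1 and 320 without replicate 2. It was 94, 4 and 29 without control replicates 1, 3 and 4. It was 0 without control replicate 2 or 5 or 162 µg replicate 3, 4 or 5 (limma, while 3195 genes had an unadjusted p under 0.05 with all arrays). Each of the 14 called genes of the paragraph above lost its call in 6 or 7 of 10 such runs, with adjusted p up to 0.262. With every spot's own background the count was 0, within scan date 1 it was 13 and within scan date 2 it was 311. Without the 3 arrays rich in muscle transcripts it was 0, and with the covariate 0. Of those muscle arrays 1, 162 µg replicate 5 of day 1, belongs to this group, and the skeletal muscle list had slide medians from −0.13 to 3.90 (adjusted p = 0.0764).

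Of the lists at 162 µg on day 1, 12 shifted up and 3 down, and 0 of the 15 held with an estimated correlation. Acute phase proteins had 5 of 19 members up (10 adjusted over the list alone; median 0.44, 5 of 5 slides, adjusted p = 1.2e-08, and adjusted p = 0.742 with an estimated correlation), and fry called this list (adjusted p = 0.0414). CC chemokines had 2 of 18 up (9 adjusted over the list alone; median 0.53, 4 of 5 slides, adjusted p = 3.7e-05, and adjusted p = 0.869 with an estimated correlation), including Ccl4 at 1.51. CXC chemokines were higher on 4 of 5 slides (0 of 13 called, 4 adjusted over the list alone, adjusted p = 0.00533, and adjusted p = 0.943 with an estimated correlation). So were cytokines (Csf2 0.64 called of 15, 6 adjusted over the list alone, adjusted p = 0.00680, and adjusted p = 0.869 with an estimated correlation). Cell division genes (0 of 38 called, 7 adjusted over the list alone; median 0.27, 3 of 5 slides, adjusted p = 1.2e-08) and interferon response genes (0 of 33, 2 adjusted over the list alone; median 0.21, 5 of 5 slides, adjusted p = 5.2e-06) each had adjusted p = 0.982 with an estimated correlation.

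Immune cell lists were higher at 162 µg on day 1 with few members called. T cell markers had a median of 0.17 (0 of 20 called, 3 adjusted over the list alone; 4 of 5 slides, adjusted p = 3.1e-04, and adjusted p = 0.982 with an estimated correlation) and dendritic cell genes 0.13 (0 of 20, 2 adjusted over the list alone; 5 of 5 slides, adjusted p = 0.00462). Adjusted p was 0.943 with an estimated correlation. Neutrophil markers (Lcn2 called of 24, 4 adjusted over the list alone; median 0.24, 4 of 5 slides, adjusted p = 0.00956), B cell markers (0 of 17, 1 adjusted over the list alone; median 0.22, 4 of 5 slides, adjusted p = 0.0187) and NK cell markers (0 of 15, 0 adjusted over the list alone; median 0.15, 3 of 5 slides, adjusted p = 0.0187) each had adjusted p = 0.993 with an estimated correlation. Lysosome genes were higher by a median of 0.11 (Gpnmb called of 34, 9 adjusted over the list alone; 4 of 5 slides, adjusted p = 0.0394). Adjusted p was 0.982 with an estimated correlation. Endothelial markers were lower on 5 of 5 slides (median −0.18, 0 of 22 called, 0 adjusted over the list alone, adjusted p = 6.8e-05). Adjusted p was 0.943 with an estimated correlation. So were fibroblast markers (median −0.11; Pdgfra −0.63 called of 22, 5 adjusted over the list alone; adjusted p = 0.0331). Adjusted p was 0.943 with an estimated correlation. Ciliated cell markers were lower on 3 of 5 slides (median −0.15, 0 of 23 called, 0 adjusted over the list alone; adjusted p = 0.0206). Adjusted p was 0.993 with an estimated correlation.

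At 54 µg on day 1, 0 genes were called by limma (646 at an unadjusted p under 0.05, smallest adjusted p 0.647). Saa3 averaged −2.82 ± 0.44 (log2 ratio to reference, mean ± standard deviation) against −2.65 ± 0.95 in control mice. Matrix, fibrosis and remodelling genes were lower as a list on 5 of 5 slides. Their median was −0.13, with 0 of 56 called and 2 adjusted over the list alone (adjusted p = 3.8e-05). Adjusted p was 0.742 with an estimated correlation. Complement genes were also lower (median −0.14, 4 of 5 slides, adjusted p = 0.00842). Adjusted p was 0.943 with an estimated correlation. Ciliated cell markers (median −0.16, lower on 3 of 5 slides, adjusted p = 6.2e-04), NK cell markers (−0.07, 3 of 5, 0.0213), fat (−0.45, 4 of 5, 0.0305) and, upward, B cell markers (0.08, 3 of 5, 0.0386) each had adjusted p = 0.993 with an estimated correlation. Other than in the matrix list, 0 members of these lists were called, also adjusted over the list alone, and fry called 0 lists at this dose.

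**Figure D2:**
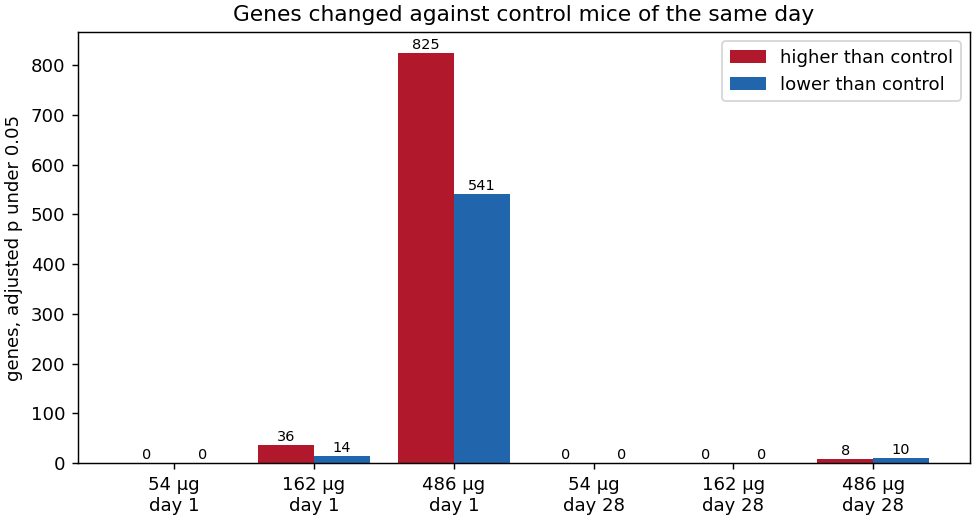
Number of genes past an adjusted p of 0.05 in each comparison of a dose with control, by day and direction. On day 1 the counts were 0, 50 and 1366 at 54, 162 and 486 µg, and on day 28 they were 0, 0 and 18.

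On day 28 at 486 µg, genes of the circadian clock were among the 18 genes called. Dbp, a clock-controlled transcription factor, rose 5.09-fold (2.35 ± 0.31, adjusted p = 7.8e-04), and the clock genes Nr1d2 and Hlf rose 1.98-fold (0.99 ± 0.18, adjusted p = 0.0136) and 1.96-fold (0.97 ± 0.18, adjusted p = 0.0142). Arntl, the clock activator also called Bmal1, fell 2.07-fold (−1.05 ± 0.15, adjusted p = 8.9e-04) and Nfil3, a repressor that opposes Dbp, fell by 0.66 ± 0.13 (adjusted p = 0.0233). Outside the clock, Tspan4, a tetraspanin, rose by 0.83 ± 0.12 (adjusted p = 0.00174), Rmdn1 by 0.43, Ankrd39 by 0.39 and Mzt2 by 0.31. Falls were Rasl11a (−0.66, adjusted p = 0.0171), Ccnjl (−0.59, 0.00463), Adam17, the protease that sheds Tnf (−0.53, 0.0348), Dtx4 (−0.46, 0.00382), Ago2 (−0.40, 0.00389) and Tmem167b (−0.27, 0.0165). Each was on the same side on 5 of 5 slides.

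The day 28 group means of Dbp went from −1.01 ± 0.16 in control mice to 0.14 ± 0.35, 0.78 ± 0.33 and 1.34 ± 0.21 (log2 ratio to reference, mean ± standard deviation) at 54, 162 and 486 µg. Arntl went from 0.66 ± 0.27 to 0.28 ± 0.22, 0.09 ± 0.17 and −0.39 ± 0.12. At 54 and 162 µg neither was called. On day 1 the Dbp means were −0.70 ± 0.96, −0.16 ± 0.71, 0.12 ± 0.45 and 0.01 ± 0.66, and Dbp was not called. The day 1 means of Arntl were 0.59 ± 0.53, 0.42 ± 0.38, 0.17 ± 0.20 and 0.03 ± 0.26, and Arntl fell at 486 µg on day 1 as well (by 0.56). The circadian list at 486 µg on day 28 had 3 of 18 members up and 2 down (9 adjusted over the list alone, 6 up and 3 down). Its median was 0.21 on 4 of 5 slides and 0.24, 0.05 and 0.21 on the 3 scan dates (adjusted p = 0.0343). Adjusted p was 0.869 with an estimated correlation.

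**Figure D3:**
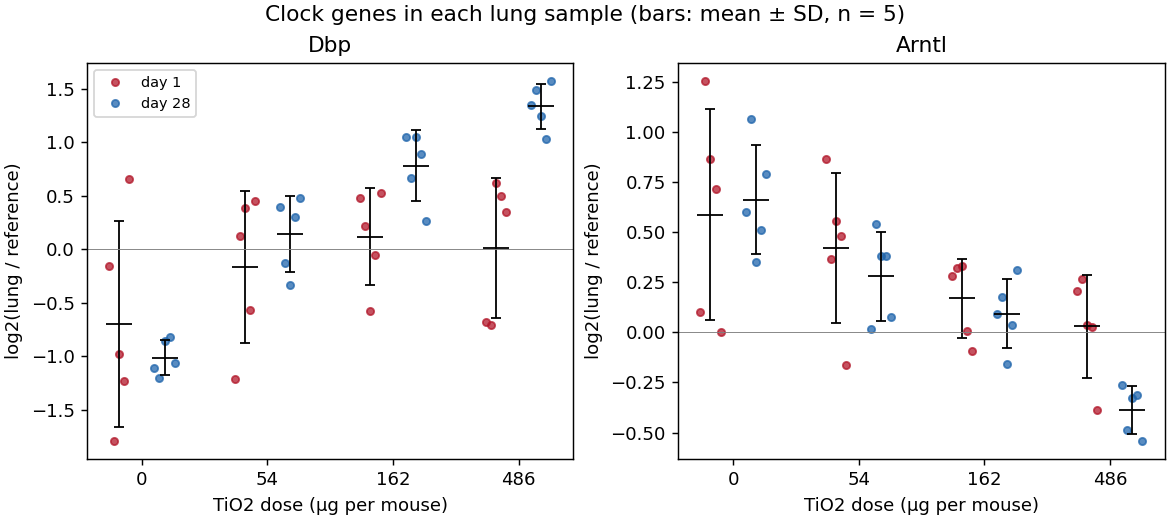
Log2 ratio of lung to reference RNA for clock genes on each array, by dose (µg) and day, with group means and standard deviations. On day 28 Dbp rose from −1.01 in control mice to 1.34 at 486 µg and Arntl fell from 0.66 to −0.39.

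The day 28 count at 486 µg was 18 genes (8 up, 10 down; 15 with a symbol), all 18 with 1 sign on the 5 slides, and 5 with every spot's own background. It was 8, 9, 11 and 11 without control replicates 1, 2, 4 and 5, and 30, 10 and 9 without 486 µg replicates 1, 4 and 5. It was 0 within scan date 1, within scan date 2 and with the covariate (limma, while 2107 genes had an unadjusted p under 0.05 in all arrays). Dbp, Arntl, Tspan4, Ccnjl, Dtx4 and Ago2 stayed past the threshold whichever of the 10 arrays was left out. The other 9 genes with a symbol lost the call in 5 (Nr1d2, Mzt2), 6 (Hlf, Rasl11a, Tmem167b), 7 (Rmdn1, Nfil3), 8 (Ankrd39) or 9 (Adam17) of 10 runs, with adjusted p up to 0.227. With the covariate, Dbp was 2.17 higher (adjusted p = 0.0599) and Arntl 0.98 lower (adjusted p = 0.0599).

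The panel of 30 genes fixed in advance had 0 members called at any dose of day 28, where 27 were measured. At 486 µg acute phase proteins had 0 of 19 members called (list adjusted p = 0.927), and matrix, fibrosis and remodelling genes 0 of 56 and 0 adjusted over the list alone, with a median of −0.04 (list adjusted p = 0.190). Neutrophil markers were higher as a list (0 of 24 called, 0 adjusted over the list alone; median 0.18, 4 of 5 slides, adjusted p = 0.00250). Adjusted p was 0.982 with an estimated correlation. Club and secretory airway cell markers were lower (0 of 20 called, 0 adjusted over the list alone; median −0.28, 4 of 5 slides, adjusted p = 0.0121, and adjusted p = 0.993 with an estimated correlation), with Scgb1a1 at −0.36, Bpifa1 at −1.20 and Reg3g at −1.56.

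At 54 and 162 µg on day 28, limma called 0 genes (1518 and 1740 at an unadjusted p under 0.05, smallest adjusted p 0.383 and 0.0792). Cholesterol genes were higher as a list on 5 of 5 slides at 54 µg (median 0.08, adjusted p = 0.0236, and adjusted p = 0.993 with an estimated correlation) and at 162 µg (median 0.14, adjusted p = 2.8e-05). Adjusted p was 0.943 with an estimated correlation. At 162 µg the circadian list was also higher (median 0.15, 5 of 5 slides, 6 adjusted over the list alone, adjusted p = 0.0294, and adjusted p = 0.869 with an estimated correlation). So were immediate early genes, which respond to tissue handling (median 0.16, 4 of 5 slides, adjusted p = 0.0149). Adjusted p was 0.982 with an estimated correlation. Skeletal muscle genes were higher there on 3 of 5 slides, with slide medians from −0.15 to 5.68 (adjusted p = 0.00189). Adjusted p was 0.993 with an estimated correlation. At 54 µg cell division genes (median 0.18, 4 of 5 slides, adjusted p = 1.3e-04) and red blood cell markers (0.27, 5 of 5, 0.0392) were higher, each with adjusted p = 0.993 with an estimated correlation. NK cell markers were lower at 54 µg (median −0.12, 4 of 5 slides, adjusted p = 0.00594) and 162 µg (−0.11, 3 of 5, 0.00505), both with adjusted p = 0.982 with an estimated correlation. Ciliated cell markers were higher on 4 of 5 slides (0.18, adjusted p = 0.0187, and 0.13, adjusted p = 0.0353), both with adjusted p = 0.993 with an estimated correlation. Other than the circadian list at 162 µg, the lists called at these 2 doses had 0 members called adjusted over the list alone. Without single arrays or within 1 scan date the gene counts stayed 0 at both doses, and at 162 µg 3 genes were called without the 5 arrays whose background fit had failed.

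The difference between days was tested directly as the 486 µg effect of day 28 minus that of day 1. Acute phase and chemokine transcripts were among those with a lower effect on day 28. The differences were Saa3 −4.77 ± 1.22 (adjusted p = 0.0334), Timp1 −3.48 ± 0.84 (0.0271), Saa1 −2.96 ± 0.72 (0.0267), Cxcl5 −2.57 ± 0.70 (0.0445) and Hmox1 −2.45 ± 0.53 (0.0172). Panel genes called in the same direction were Ccl7 (−2.77), Ccl2 (−2.72), Spp1 (−2.22), Lcn2 (−2.09), Saa2 (−1.95), Cxcl1 (−1.94), Orm1 (−1.64), Ccl17 (−1.41) and Gpnmb (−1.09). Without day 1 486 µg replicate 4 the differences were −5.66 for Saa3, −4.26 for Timp1, −3.57 for Saa1, −3.41 for Ccl7 and −3.39 for Ccl2, and without day 1 control replicate 1 that of Saa3 was −5.48. Dbp was 0.71 above control on day 1 and 2.35 on day 28 (difference 1.63 ± 0.44, adjusted p = 0.0434). Effects that were below control on day 1 and above it on day 28 were those of Rab5c, an endosomal GTPase (−1.16 and 1.03, difference 2.20 ± 0.55, adjusted p = 0.0318), Rmrp (−1.25 and 0.61, 1.87 ± 0.44, 0.0237), D430042O09Rik (−0.77 and 0.78, 1.55 ± 0.40, 0.0332) and Taf15 (−0.81 and 0.72, 1.53 ± 0.35, 0.0226). For several of these the control mice themselves differed between days. Hmox1 had control means of −3.18 on day 1 and −1.91 on day 28 beside 486 µg means of −1.47 and −2.65, and Rab5c 1.15 and −0.70 beside −0.02 and 0.33. Control mice of day 28 were also lower in Taf15 (by 1.13, adjusted p = 0.0293) and D430042O09Rik (by 1.27, 4.8e-05). With the covariate, the day 1 effects were −0.05 for Rab5c, −0.05 for Taf15 and 0.45 for Hmox1. Cxcl5 stood above background on 1 of 5 arrays of 486 µg on day 28, so its difference is only approximate.

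The 486 µg effect differed between days for 538 genes (211 higher, 327 lower on day 28; 435 with a symbol), and limma called 0 for 54 µg (999 at an unadjusted p under 0.05) and 0 for 162 µg (2307). With every spot's own background the count was 3, without the slide block 103, and with the arrays of the 4 groups alone 90. Within scan date 1 it was 94 and within scan date 2 0, without the 5 arrays whose background fit had failed 0, and with the covariate 0. Leaving out day 1 arrays gave 133, 115 and 1280 without 486 µg replicates 1, 2 and 4. They gave 232, 348 and 209 without control replicates 2, 4 and 5. Leaving out day 28 arrays gave 247 and 133 without 486 µg replicates 3 and 4, and 219, 358, 357 and 147 without control replicates 1, 2, 3 and 4. For the 162 µg effect, 25 genes were called without day 1 162 µg replicate 1 and 3 without day 28 162 µg replicate 5. Of the 19 genes with differences given above, Spp1 kept its call in all 20 runs, and Hmox1 lost it without day 1 486 µg replicate 2 (adjusted p = 0.0510). Saa2 lost it in 2 runs, Rmrp and Taf15 in 4, Cxcl1 in 5, Timp1 and Saa1 in 7 and Lcn2 in 9. The call was lost for Rab5c and Ccl2 in 12, Saa3 and D430042O09Rik in 13, Dbp, Orm1 and Ccl7 in 14, Cxcl5 in 16, Gpnmb in 18 and Ccl17 in 19, with adjusted p of these genes up to 0.121. With the covariate D430042O09Rik turned to −0.17 (adjusted p = 0.922).

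Lists whose 486 µg effect differed between days were all lower on day 28. Acute phase proteins had 8 of 19 members called (11 adjusted over the list alone; adjusted p = 3.8e-08, and adjusted p = 0.799 with an estimated correlation), and fry called this list (adjusted p = 0.0414). CC chemokines (6 of 18, 7 adjusted over the list alone, adjusted p = 0.00713), CXC chemokines (2 of 13, 4, 0.0331), lysosome genes with Cd63 at −0.99 (3 of 34, 10, 0.0331) and cholesterol genes (3 of 26, 9, 3.1e-04) each had adjusted p = 0.982 with an estimated correlation. Cytokines with Il11 at −0.58 (1 of 15, 8 adjusted over the list alone, adjusted p = 0.0138) and matrix genes with Spp1, Timp1 and Mmp14 (3 of 56, 9, 0.0187) each had adjusted p = 0.943 with an estimated correlation. Cell division (0 of 38, 0 adjusted over the list alone, adjusted p = 8.8e-05), interferon response (3 of 33, 3, 0.0168) and unfolded protein response genes with Hspa5, an endoplasmic reticulum chaperone, at −1.29 (1 of 21, 1, 0.0333) each had adjusted p = 0.993 with an estimated correlation.

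The step from 162 to 486 µg was also tested directly. On day 1 limma called 1 gene, a feature without a symbol that was 0.76 lower at 486 µg on 5 of 5 slides (adjusted p = 0.0166, with 959 at an unadjusted p under 0.05). On day 28 it called 0 (813 at an unadjusted p under 0.05, smallest adjusted p 0.783). The day 1 count was 0 without 486 µg replicate 1 or 2 or 162 µg replicate 2, 4 or 5. It was 4 without 486 µg replicate 3 and 11 without 486 µg replicate 5. Across 20685 genes, the effects of the 2 doses correlated with r = 0.817 on day 1. Unchanged doses sharing the same control mice gave a mean of 0.511 ± 0.170 (standard deviation) and at most 0.852 in 100 simulations. With the control mice split between the doses, r was 0.228 to 0.624 (median 0.453) over 10 splits. On day 28 r was 0.606 against a simulated mean of 0.477, and 0.134 to 0.383 (median 0.221) with split controls. Genes are not independent replicates in these values. Of the 50 genes called at 162 µg on day 1, 45 were called in the same direction at 486 µg. The 2 counts share control mice, which raises the overlap, and its size without a change was not computed.

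Between days, 4 genes were called in the same direction at 486 µg, Arntl, Ccnjl, Tspan4 and 1 without a symbol, and 1 gene was called in opposite directions. From the counts up and down, 0.579 would be shared by chance. Fisher's exact test gave p = 0.00426. In it, day 28 calls whose day 1 effect had the other sign counted as not called, so it is no test of that 0.579. It also treats genes as independent. At an adjusted p under 0.01 the shared genes were 2 (Fisher's exact test p = 0.00335), and without the slide block 2 (Fisher's exact test p = 0.0257).

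Control mice themselves differed between the days. Higher on day 28 were Ncl, nucleolin (1.52 ± 0.18, adjusted p = 0.00242), Rab27a (1.48 ± 0.12, 9.4e-05), Ier3 (1.45 ± 0.16, 0.00221), the nuclear RNA Malat1 (1.38 ± 0.28, 0.0360) and Slc35e3 (1.32 ± 0.24, 0.0246). Lower were the liver-made plasma proteins Alb, albumin (−2.16 ± 0.32, adjusted p = 0.00966), Serpina1d (−2.05 ± 0.29, 0.00765) and Ahsg (−1.77 ± 0.36, 0.0360), with Rab5c (−1.85 ± 0.14, 8.1e-05) and Ube2s (−1.71 ± 0.30, 0.0233). In all, 230 genes differed (132 higher, 98 lower; 186 with a symbol). These 2 days also differ in slides, since each slide held 1 day only. All 25 liver transcripts of a list made after the data were seen, Alb, Serpina1d and Ahsg among them, were lower in day 28 control mice, 4 of them called. Their mean log2 deviation was −0.75 ± 0.08 (standard deviation) in those mice against 0.01 ± 0.56 in day 1 control mice, and within groups the 25 correlated with a mean r of 0.779. Of the 230 genes, 87 were also among the 538 whose 486 µg effect differed between days. Another tally was 72 of the 230 among the 1366 changed at 486 µg on day 1, 71 of these in the direction in which day 28 control mice differed. These comparisons share control mice, which raises both overlaps, and their size without a change was not computed.

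The control comparison counted 101 and 64 genes without day 1 replicates 1 and 5, 47, 46, 108 and 77 without day 28 replicates 1, 3, 4 and 5, and 23 with every spot's own background. Ncl, Rab27a, Ier3, Alb, Serpina1d and Rab5c kept the call in all 10 runs with 1 mouse left out, while Ube2s lost it in 5, Slc35e3 in 6, Ahsg in 7 and Malat1 in 8.

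**Figure D4:**
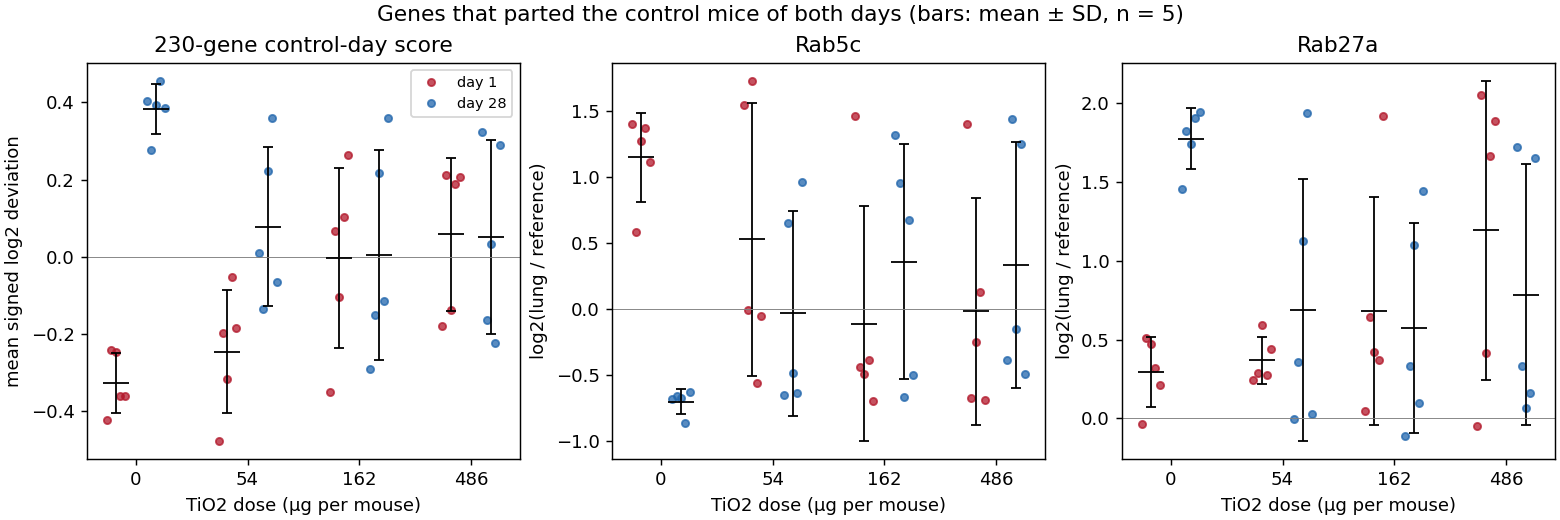
Mean signed log2 deviation of the 230 genes that differ between control mice of the 2 days, and log2 ratio of lung to reference RNA for Rab5c and Rab27a, for each array by dose (µg) and day, with group means and standard deviations. The scores of control mice of the 2 days average −0.33 and 0.38, and the treated group means lie between −0.25 and 0.08, where the genes were chosen for parting these control mice.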

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

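The outlier screen and the tests of the difference between days were fixed before the data were examined, as were the tests on other groupings of the arrays, while the swaps within slides and all tests that weigh explanations in the last 3 paragraphs were chosen after the results were seen. The screens of the liver transcripts and of the score of the genes that part control mice are exceptions, since both gene sets were made after the data were seen.

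Single mice stood apart from their group in 22 of 252 screens of 5 values, where 12.6 would do so by chance. Among panel genes, as log2 differences from the control array of the same slide, these were Chil3 at 54 µg on day 1, replicate 1 (0.87, others −0.28 to −0.12), and on day 28, replicate 4 (−0.85, others −0.03 to 0.20). Saa3 at 162 µg on day 1 was −2.12 in replicate 1 and 4.88 to 7.35 in the other 4. As a log2 ratio to reference, Saa3 was −3.27 in that mouse and 1.44 to 3.92 in the other 162 µg mice. The control of its slide stood at −1.16, the highest of the day 1 controls, so both arrays made this difference. Ccl17 at 486 µg on day 1 was 0.16 in replicate 4 and 1.77 to 2.04 in the others. Orm1 on day 28 was 0.65 at 54 µg, replicate 1 (others −0.35 to −0.07), and 1.40 at 162 µg, replicate 1 (others −0.15 to −0.01). Both of these were set against the same control array, replicate 1 of day 28. At 162 µg on day 28, Cxcl10 was 0.97 in replicate 4 (others −0.23 to 0.02) and the surfactant gene Sftpc −1.26 in replicate 3 (others 0.14 to 0.53).

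Transcripts of other tissues stood apart in single samples, as mean log2 deviations of the members of a list. Liver transcripts on day 28 were at 0.88 at 54 µg, replicate 2 (others −0.68 to −0.30), 2.11 at 162 µg, replicate 1 (others −0.23 to 0.34), and 0.067 at 486 µg, replicate 4 (others −0.72 to −0.50). Skeletal muscle genes were at 3.74 at 162 µg on day 1, replicate 5 (others −0.53 to −0.31), 3.08 at 54 µg on day 28, replicate 4 (others −0.38 to −0.03), and 4.56 at 162 µg on day 28, replicate 3 (others −0.44 to −0.08). Smaller gaps stood at 54 µg on day 1, replicate 2 (0.025, others −0.45 to −0.33), and 486 µg on day 28, replicate 5 (0.027, others −0.44 to −0.31). Heart genes were at 1.04 in day 28 control replicate 2 (others −0.21 to 0.03), and thymus genes at 1.20 in day 28 control replicate 5 (others −0.47 to −0.03) and 1.31 at 162 µg on day 28, replicate 3 (others −0.28 to −0.08). Red blood cell genes on day 28 were at −0.49 in control replicate 5 (others 0.03 to 0.22), −0.086 at 54 µg, replicate 5 (others 0.30 to 0.40), and −0.63 at 486 µg, replicate 5 (others 0.08 to 0.26).

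The effect of 486 µg differed between days for 538 genes in the test of the difference itself (day 28 minus day 1). The named genes were Rab5c 2.20, Rmrp 1.87, Dbp 1.63, D430042O09Rik 1.55, Taf15 1.53, Saa3 −4.77, Timp1 −3.48, Saa1 −2.96, Cxcl5 −2.57, Hmox1 −2.45, Saa2 −1.95, Lcn2 −2.09, Orm1 −1.64, Cxcl1 −1.94, Ccl2 −2.72, Ccl7 −2.77, Ccl17 −1.41, Spp1 −2.22 and Gpnmb −1.09.

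Each count was compared with those from other groupings of the same arrays, 100 drawn of 126 with the real one included. At 486 µg on day 1, 3 of 100 groupings gave at least the real 1366 genes (highest other 1898), and at 486 µg on day 28 1 gave at least 18 (highest other 1). For the difference between days at 486 µg 1 gave at least 538 (highest other 191), and between control mice 1 gave at least 230 (highest other 44). The share of these groupings was under 0.05 for all 4 counts. All were run under the background handling chosen after the first counts had been seen. Under that handling chance was excluded only for the difference between days and for the control comparison. Those of the 2 counts of a dose against control were drawn without regard to slide, those of the difference between days exchanged whole slides, and each control array sat on a slide of its own. For comparisons within a day, swaps of the 2 arrays within slides give 16 groupings, too few for a share under 0.05. With slides kept, chance was therefore not excluded for the 2 counts of a dose against control. In these swaps the real 1366 at 486 µg on day 1 stood against a highest other of 992, the 18 on day 28 against 1, the 50 at 162 µg on day 1 against 305, and the 1 of the day 1 step against 1418. Chance was not excluded at 162 µg on day 1, where 10 of 100 groupings gave at least 50 genes (highest other 916). Nor was it for the day 1 step from 162 to 486 µg, where 19 gave at least 1 gene (highest other 2067). For the 6 counts of 0, all 100 groupings gave at least as many, with highest others of 31 at 54 µg on day 1, 1 for the difference between days at 162 µg, and 0 at 54 and 162 µg on day 28, for the day 28 step and for the difference between days at 54 µg. Groupings that call 916 or 2067 genes point to a structure of the day 1 samples. Mice with an absent or weaker response may be part of it, which was not tested: 1035 genes were called without 162 µg replicate 1 and 2428 without 486 µg replicate 4.

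The genes that differ between control mice of the 2 days also varied together within the 6 treated groups, which that comparison does not use. Their mean signed correlation there was 0.342, against a 95th percentile of 0.0346 and a maximum of 0.0446 in 1000 random lists, so a state shared by samples of any dose may be a source of this pattern. Slides held 44.5% of the variance of the score within groups (31.1 to 53.9% without any 1 slide; permutation p = 0.0435, 25.1% expected), which leaves slide or scan date open. Mice of the 2 days differed in the score by 0.709 ± 0.046 in controls, 0.324 ± 0.116 at 54 µg (exact permutation p = 0.0238), 0.008 ± 0.160 at 162 µg (exact permutation p = 0.968) and −0.007 ± 0.143 at 486 µg (exact permutation p = 0.976). The last 2 values go against a day effect of the control size at every dose, but the control value is raised by choosing the genes on these mice, so that a smaller effect of the day stays open.

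The clock genes raised or lowered at 486 µg on day 28 could reflect another time of day at tissue collection. Phases in the daily cycle were written after the results were seen, for 15 measured members, while 3 others were given none. All 15 had the sign of their phase. So did the 10 of them that were not called, from Nr1d1 (0.92), Per2 (0.52) and Per1 (0.42) to values near 0 (Cry1 −0.10, Npas2 −0.09, Ciart 0.00). The circadian list had been called at this dose and day, with more members past the adjustment over the list alone than the 5 called. These 10 were therefore not independent of what prompted the test. The mean phase-signed difference of these 10 was 0.30 ± 0.08 and above 0 on 5 of 5 slides (exact one-sided permutation p = 0.0312 with swaps within slides, the smallest they can give), which does not treat genes of 1 clock as independent. The state that parts control mice was excluded as the whole cause, since the median size of the 5 called genes went from 0.988 to 0.885 with its score as a covariate (standard errors 0.176 and 0.197), where 0 of 5 calls held with a like fold and a wider error. A direct effect of dose on the clock was not tested apart from collection time and stays open.

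The acute phase genes raised at 486 µg on day 1 were set against more liver RNA in those samples: the median of 25 liver transcripts was 0.434 higher, against 3.08 ± 0.51 for Saa1. More liver RNA with an unchanged Saa1 content was therefore excluded as the source of the size of the Saa1 change. A rise of Saa1 inside the liver, carried in by that RNA, had no formal test. As log2 ratios to reference, Alb at 486 µg was 1.92, 3.69, 2.94, 4.34 and 3.97 in replicates 1 to 5, and Saa1 3.14, 3.23, 3.01, 0.60 and 3.34. Replicate 4 was also low in Ccl2 (−4.42) and Timp1 (−2.18), so its low Saa1 tells little of the source. At 162 µg, Alb was 3.69, 1.20, 3.88, 0.99 and 2.16, and Saa1 −0.51, 1.59, 3.59, 3.59 and 3.84. Replicate 1 of that dose was low in Timp1 (−3.18) as well. Mice differed in their response, so these values do not decide the question, and a rise in the liver stays open. The state that parts control mice was excluded as the whole cause, since the median of the 9 called genes was 1.79 without and 1.79 (1.786) with its score as a covariate, and 4 of 9 kept the call with wider errors (standard errors 0.305 and 0.385). A response of lung to the dose, which the design names, is consistent with these values and remains a hypothesis.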

How the results depend on the processing

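Other background handlings, the covariate and the runs without failed or muscle-rich arrays were chosen after seeing the data. The other alternatives were fixed before, and where no cause is given, the cause was not tested. Normexp on every spot's own background, the handling first planned, gave 13 genes at 486 µg on day 1, 0 at 162 µg on day 1, 5 at 486 µg on day 28, 3 for the difference between days at 486 µg, 23 between control mice and 0 for the day 1 step from 162 to 486 µg. Its maximum likelihood fit gave 4 at 486 µg on day 28 and otherwise equal counts (13, 0, 3, 23 and 0). Without the 5 arrays with a failed fit there were 231 genes at 486 µg and 425 at 162 µg on day 1, 3 at 162 µg on day 28, 0 and 20 for the difference between days at 486 and 162 µg, 66 between control mice and 0 for the day 1 step. Without the slide block there were 670 genes at 486 µg and 16 at 162 µg on day 1, 11 at 486 µg on day 28 and 103 for the difference between days. With slide as a random block there were 135 at 162 µg on day 1 and 1 at 162 µg on day 28. At 162 µg on day 28, 2 genes were called with no background correction and 2 with Cy5 alone, and Cy5 alone gave 233 for the difference between days. The software's log ratio gave 9 genes at 162 µg on day 1, 82 between control mice and 0 for the day 1 step. At 162 µg on day 1, no filter gave 32 genes and a filter on all 40 arrays 88. With the arrays of the compared groups alone, 0 genes were called at 486 and at 162 µg on day 1 and for the day 1 step, 4 and 5 at 162 and 486 µg on day 28 and 90 for the difference between days. These fits have fewer degrees of freedom and also take no spread from the other groups. Timp1, for example, had standard deviations of 0.15 to 0.26 on day 28, against 1.63 at 486 µg on day 1. The part of each in the lower counts was not tested. Scan date 1 alone gave 13 genes at 162 µg on day 1, 0 at 486 µg on day 28 and 94 for the difference between days. Scan date 2 alone gave 311 at 162 µg on day 1 and 0 at 486 µg on either day, for the difference between days and for the day 1 step. Scan date 3 alone was not run, since it holds 1 slide per day. With the score of the genes that part control mice as a covariate, 65 genes were called at 486 µg on day 1, and 0 at 162 µg on day 1, at 486 µg on day 28 and for the difference between days, where D430042O09Rik reversed to −0.17 (adjusted p = 0.922). The genes of that score were chosen on the control mice, so it parts control from treated arrays by selection, and a call lost with it is not thereby explained. Without the 3 muscle-rich arrays 0 genes were called at 162 µg on day 1. The counts at 162 and 486 µg on day 1, at 486 µg on day 28, for the difference between days at 486 µg and between control mice stayed within 1.5 times under the authors' matrix, the mean of probes, the intensity trend and a background limit of 100 units. Quantile normalization of the average signals between arrays leaves the log ratios as they are, so its equal counts say nothing about stability.

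Leaving out each array in turn gave 266 to 2428 genes at 486 µg and 0 to 1035 at 162 µg on day 1, and 8 to 30 at 486 µg on day 28. It gave 115 to 1280 and 0 to 25 for the difference between days at 486 and 162 µg, 46 to 284 between control mice and 0 to 11 for the day 1 step, and the other counts of 0 stayed 0. In these runs 689 of 1080 calls of single genes held, where only the genes of largest change and the panel were run, not the list members. Of 89 such calls with all arrays, 83 held with the authors' matrix, 59 with the software's log ratio, 69 with Cy5 alone, 9 with every spot's own background and 48 without the 5 failed arrays. Of the 79 outside the control comparison, 51 held without the slide block, 42 in scan date 1, 11 in scan date 2 and 11 with the covariate. Of 245 list tests, 56 were called; an estimated correlation gave 0 and fry 6. Genes shared by the days at 486 µg went from 4 to 2 at an adjusted p under 0.01 and to 2 without the slide block. The correlation of the 162 and 486 µg effects went from 0.817 to 0.228, 0.453 and 0.624 (lowest, median and highest of 10 control splits) on day 1 and from 0.606 to 0.134, 0.221 and 0.383 on day 28; shared control mice raise the unsplit values. Signal over background limits low genes: 20726 of 32111 features were tested. No paired analysis by animal was possible, since each mouse had 1 array and belonged to 1 group. Slide served as the block.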

Other observations

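No test in this part weighs an explanation, and its lists were fixed before the data were examined.

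Epithelial and vascular markers did not shift as lists at 486 µg on day 1, although single members did. Aqp5, a water channel of type I pneumocytes, was 0.93 higher and Pdpn 0.38 higher, while Cav1, of caveolae, fell by 0.52 and Sema3e by 0.41, of 13 type I pneumocyte markers measured (6 adjusted over the list alone; list adjusted p = 0.190). Slc26a4, the anion exchanger pendrin, rose by 1.97 and Aldh1a1 fell by 0.68 of 20 club and secretory cell markers (3 adjusted over the list alone; list adjusted p = 0.699). Tppp3 fell by 0.29 of 23 ciliated cell markers (1 adjusted over the list alone; list adjusted p = 0.443). Type II pneumocyte markers (0 of 15 called, 0 adjusted over the list alone; list adjusted p = 0.823) and endothelial markers (0 of 22, 0, 0.0549) had no member called by limma.

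Stress genes moved singly on that day as well. Of the p53 targets, Bax (0.71), Gdf15 (0.64), Aen (0.57) and Gadd45g (0.56) rose, 4 of 19 (4 adjusted over the list alone; list adjusted p = 0.335). The endoplasmic reticulum chaperone Hspa5 (0.84) and Sdf2l1 (0.87) rose, 2 of 21 unfolded protein response genes (2 adjusted over the list alone; list adjusted p = 0.217). Ier3 (1.49) and Junb (0.79) rose and Jun fell by 0.33 among 19 immediate early genes (5 adjusted over the list alone; list adjusted p = 0.842). Ier3 also differed between control mice, with mean log2 ratios to reference of −1.48 on day 1 and −0.03 on day 28. Of 18 complement genes C3 and C3ar1 rose (3 adjusted over the list alone; list adjusted p = 0.474). Of 13 glucocorticoid response genes Lcn2 and Mt2 rose (2 adjusted over the list alone; list adjusted p = 0.755; median −0.05, mean 0.18). Of 18 circadian genes Bhlhe40 rose by 0.67 and Arntl fell by 0.56 (2 adjusted over the list alone; list adjusted p = 0.591; median −0.08, mean 0.02).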
